A study of Dactylorhiza majalis with 12 samples.

How the data were processed

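The series holds 12 RNA-seq libraries of protocorms of Dactylorhiza majalis, 4 each from field symbiotic, in vitro symbiotic and in vitro asymbiotic growth. Per the labels' protocols, tissue was homogenized in liquid nitrogen, RNA was extracted with the NucleoZol reagent and purified on magnetic beads, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, FastQC 0.11.7 and Trimmomatic 0.38 were used on the reads. The assembler settings, the aligner and the counting program are not given in the sources used here. The authors deposited a table of counts per transcript, whole numbers that were not normalized, whose column names, per the file headers, mark the values as fragments after a step named noribo and a step named clean. Whether the deposited counts are direct counts or rounded estimates is not known, and reads shared between similar transcripts, or between antisense partners, may have been split in a way that could not be checked. Transcript names follow the Trinity assembler and carry the prefixes LF (33798 transcripts) or MR (74475 transcripts), whose meaning is not given in the sources used here. No reference genome or annotation was used. Counts could not be divided by organism, so transcripts of a fungus, if the table holds any, were tested with the others.

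Each column was tied to its library through the column name in the labels, and 0 columns were left without a sample. Groups were taken from the titles. The labels do not say whether replicates came from separate cultures, plots or seed batches, so p-values measure the spread between these libraries, which may be partly technical. Pairs of libraries of the same group differed by 14.0 to 54.4 times the variance expected from counting (chi-square per degree of freedom), so no library was counted as a repeat of another.

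Of 108273 transcripts, 4231 had no counts. Transcripts were kept with filterByExpr of edgeR (minimum count 10, minimum total 15), which left 56924 (52.6%). Scaling factors came from TMM, and a quasi-likelihood negative binomial model with 1 mean per group was fitted over the 12 libraries (edgeR 4.0.16 in R 4.3.3, 9 residual degrees of freedom, biological coefficient of variation 47.4%). Each of the 3 comparisons was a contrast of this fit, tested with the quasi-likelihood test and adjusted by the Benjamini-Hochberg method over the transcripts tested, and a transcript was called at an adjusted p below 0.05. CPM values and detection floors were computed from the deposited counts with the TMM-scaled library sizes of the transcripts kept. SEs of log2 fold changes were computed as the absolute fold change over the square root of the test statistic. Where a group was at 0 in each library, a fold is given as a lower bound against 3 counts over the group, which is 0.0496 CPM in field, 0.0476 CPM in asymbiotic and 0.0535 CPM in in vitro symbiotic libraries. Bounds and intervals cover counting error only, since the reads carried no molecular identifiers.

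The rule for named items was set for the case that nothing pairs identifiers with names. It takes the 2 identifiers that rose most and the 2 that fell most in field against asymbiotic protocorms, among called transcripts without overlap of the groups and with a mean of at least 10 CPM in the higher group. The tests, the rule, the thresholds and most alternatives were fixed before the data were examined. A set of 35 gene lists with 303 name patterns (such as symbiosis, nutrient transport and defence genes) was fixed at the same time, but 0 patterns matched the transcript names, so no list could be tested and no list result is given.

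The responses of field and in vitro symbiotic protocorms share the asymbiotic libraries. Values expected without effects were computed from 5 simulated sets of negative binomial counts with the fitted dispersions, 1 per transcript for all groups. Overlaps and correlations were computed again with the asymbiotic libraries split into disjoint pairs (6 splits). Correlations and shares of agreeing signs were computed with these pairs for the simulated counts too. Errors of the correlation and of the ratio of response sizes are jackknife SEs over the 12 libraries taken as 1 sample, not within groups. Exact permutation tests of library measures were two-sided, with 15 tests adjusted together. Alternatives were DESeq2 1.42.0, median-of-ratios scaling, library size alone, no filter and a stricter filter (at least 1 CPM in 4 libraries and 50 counts in total), fits on the compared groups alone, the replicate number as a block, and leaving out each library in turn. Alternatives that leave out libraries, and fits on the compared groups alone, kept the 56924 transcripts of the full set, because the filter admits more low counts when libraries are left out. Leaving out the 2 libraries with other names (field replicate 4 and in vitro symbiotic replicate 4, whose library names begin unlike the rest of their group), summing transcripts of a Trinity gene, and the estimate from disjoint sets of libraries were added after seeing the data.

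The code was tested on simulated counts for the real transcripts with 200 transcripts changed by known folds. In field against asymbiotic libraries it recovered 6% of 2-fold, 32% of 4-fold, 64% of 8-fold and 78% of 16-fold changes, and 5 of 56724 unchanged transcripts were called. In in vitro symbiotic against asymbiotic libraries the shares were 0, 26.0, 54.0 and 76%, with 2 false calls. In field against in vitro symbiotic libraries they were 0, 24.0, 56.0 and 80%, with 2 false calls. A response ratio set to 1.43 was recovered as 1.42, with the same dispersion simulated in each group. With only 200 changed transcripts, the adjustment was stricter than in the real comparisons with asymbiotic libraries. The shares recovered may thus be too low for those comparisons.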

Results

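RNA was sequenced from protocorms of the orchid Dactylorhiza majalis, the small tuberous bodies that orchid seeds form before they make shoots and roots. Orchid seeds carry very little stored food and in nature depend on a mycorrhizal fungus to develop. The 12 libraries fell into 3 groups of 4, which were protocorms grown in the field with fungus (field symbiotic), protocorms grown in Petri dishes with fungus (in vitro symbiotic) and protocorms grown in Petri dishes without fungus (in vitro asymbiotic). Per the labels, the in vitro symbiotic protocorms grew on agar with oatmeal powder and the asymbiotic protocorms on a complex medium with sugar, so fungus and medium changed together between these groups. No asymbiotic group was grown in the field, so fungus and growth in the field changed together between field symbiotic and in vitro asymbiotic protocorms. The table of counts listed 108273 transcripts with Trinity identifiers and paired none of them with a gene name, so transcripts are described by their counts and at most 4 identifiers are printed.

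Total counts of field symbiotic replicates 1 to 4 were 13808886, 14299745, 16980968 and 15784762. Those of in vitro asymbiotic replicates 1 to 4 were 17017703, 9353301, 23145905 and 19448548, and those of in vitro symbiotic replicates 1 to 4 were 15839766, 14209447, 12332113 and 10846005. A count of 0 in a single library allowed a level of up to 0.148 CPM (counts scaled to library size) in the deepest library and 0.325 CPM in the shallowest, counting error alone. The difference in mean total between field and asymbiotic libraries was within the spread of the libraries (exact two-sided permutation test, n = 4 and 4, p = 0.543, adjusted p = 0.543 over 15 tests of library measures).

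The asymbiotic libraries lay apart from the symbiotic libraries on the first principal component of log2 CPM, which held 38.4% of the variance. Asymbiotic libraries scored from -199.3 to -165.3 and field libraries from 117 to 131.7. The in vitro symbiotic libraries were spread widely on that component, at -27.4, -0.4, 88.8 and 142.2 for replicates 1 to 4, so field and in vitro symbiotic libraries did not separate there. The second component, with 12.9% of the variance, placed the 4 in vitro symbiotic libraries at 81.0 to 143.1 and the field libraries at -118.3 to -32.4.

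**Figure D1:**
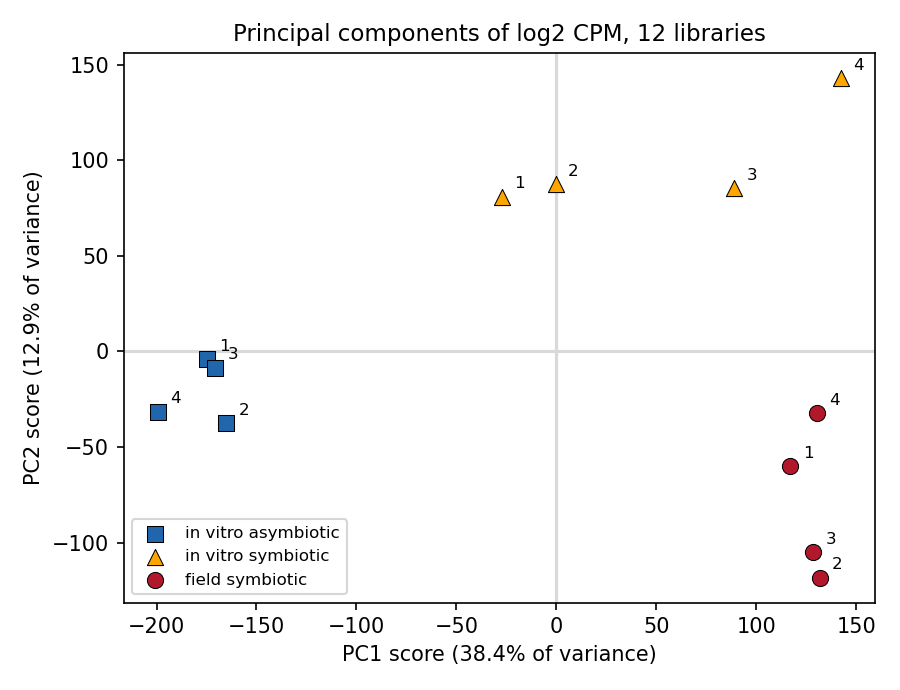
First (x axis) and second (y axis) principal component scores of log2 CPM, 1 point per library, with the replicate number beside it and the group given by colour and shape. Asymbiotic libraries lie at -199.3 to -165.3 on the first component, field libraries at 117 to 131.7, and in vitro symbiotic libraries from -27.4 to 142.2.

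The comparison of field symbiotic with in vitro asymbiotic protocorms asked which transcripts differ between a protocorm fed by a fungus in its natural habitat and one fed by the medium. Of 56924 transcripts tested, 5729 were higher and 4774 lower in field protocorms. Transcripts higher in the field had a median log2 fold change of 2.25 (4.75-fold), and transcripts lower in the field a median of -1.43 (2.70-fold lower). The medians were 2.25 and -1.43 as well when the 369 higher and 15 lower transcripts at 0 in every library of the lower group were set to their lower bounds. Changes of at least 16-fold were found for 1373 transcripts higher in the field and 240 lower in the field, by fitted fold change.

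The transcript TRINITY_LF_DN40227_c1_g1_i1 had 340 ± 167 CPM (SD, n = 4) in field protocorms and 0 in each of the 4 asymbiotic libraries. It was at least 7147-fold higher in the field against the level that 3 counts over the asymbiotic group allow (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00027). The transcript TRINITY_MR_DN70753_c0_g2_i7 had 264 ± 251 CPM (SD, n = 4) in the field and 0 in each asymbiotic library, at least 5538-fold higher (edgeR adjusted p = 0.00345). Its field level was 2.98 CPM in replicate 4 and 122 to 566 CPM in replicates 1 to 3, and the bound was 3424-fold without replicate 2. Both of these transcripts were at 0 in every asymbiotic library and at 10 or more counts in every symbiotic library. From the counts it cannot be told whether they come from the orchid or from another organism. In the other direction, TRINITY_LF_DN28561_c0_g1_i1 had 0 in each field library and 77.4 ± 26.2 CPM (SD, n = 4) in asymbiotic protocorms, at least 1559-fold lower in the field (edgeR adjusted p = 0.0230). Its call ended without field replicate 3 (adjusted p = 0.0505, the highest of 20 alternatives, which went down to 2.0e-21). TRINITY_LF_DN44157_c2_g2_i1 had 96.9 ± 148 CPM (SD, n = 4) in asymbiotic protocorms and 1 count in the 4 field libraries together (edgeR adjusted p = 0.00176). Its mean CPM in asymbiotic protocorms was 5854 times the level of 1 count over the 4 field libraries, with a 95% counting interval of 1051 to 231204. Asymbiotic replicate 3 held 6417 of its 7533 asymbiotic counts, and without that library this ratio of mean CPM to the field level was 1418 (254 to 55999) and the fitted log2 fold change -9.87 in place of -11.92. The single field count came from field replicate 1, and the log2 fold change was -13.51 without it.

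In total 10503 transcripts (18.5% of those tested) differed between field and asymbiotic protocorms at an adjusted p below 0.05, and 8589 of them by at least 2-fold. The 4 field and 4 asymbiotic values did not overlap for 24.5% of all tested transcripts, where chance gives 2.86%. The balance between higher and lower calls depended on scaling. Library size alone moved the median log2 fold change of all transcripts up by 0.12 and made 65.3% of the calls higher in the field against 54.5% with TMM. Transcripts lower in the field numbered 2918 without field replicate 3 and 3155 without asymbiotic replicate 4.

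The comparison of in vitro symbiotic with in vitro asymbiotic protocorms asked which transcripts differ with the fungus in culture. Here 3506 transcripts were higher and 2971 lower in symbiotic protocorms. Transcripts higher with the fungus had a median log2 fold change of 2.52 (5.76-fold), and transcripts lower with the fungus a median of -1.38 (2.60-fold lower). These medians were 2.52 and -1.38 with the transcripts at 0 in a whole group, 324 of them higher with the fungus, set to their bounds. At least 16-fold changes were found for 959 transcripts higher with the fungus and 83 lower.

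TRINITY_LF_DN40227_c1_g1_i1 reached 208 ± 165 CPM (SD, n = 4) in in vitro symbiotic protocorms, at least 4361-fold above the asymbiotic group (edgeR adjusted p = 0.00060), with 54.9 CPM in the lowest symbiotic library. TRINITY_MR_DN70753_c0_g2_i7 reached 22.4 ± 24.9 CPM (SD, n = 4), at least 471-fold above the asymbiotic group (edgeR adjusted p = 0.0184). That bound rested on in vitro symbiotic replicate 4, which had 59.4 CPM against 5.71 to 14.4 CPM in the others, and was 212-fold without it. With the replicate number as a block the edgeR adjusted p was 0.0660, and the call ended. TRINITY_LF_DN44157_c2_g2_i1 had 0.321 ± 0.338 CPM (SD, n = 4) with the fungus in vitro, a log2 fold change of -8.20 ± 1.5 (SE) against asymbiotic protocorms (edgeR adjusted p = 0.00575). The log2 fold change was -6.15 without asymbiotic replicate 3, which held most of its counts, and -9.24 without in vitro symbiotic replicate 2. TRINITY_LF_DN28561_c0_g1_i1 gave no call in this comparison (log2 fold change -0.02 ± 1.56 SE, edgeR adjusted p = 0.994), because its in vitro symbiotic values were 80.9 and 223 CPM in replicates 1 and 3 and 0 in replicates 2 and 4. The log2 fold change was -1.52 without in vitro symbiotic replicate 3.

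In total 6477 transcripts (11.4%) differed between in vitro symbiotic and asymbiotic protocorms, 5420 of them by at least 2-fold, and values of the groups did not overlap for 18.5% of all tested transcripts against 2.86% by chance. The count fell to 4130, 3423, 3758 and 3725 without asymbiotic replicate 1, asymbiotic replicate 4, in vitro symbiotic replicate 3 and in vitro symbiotic replicate 4, and was 10076 in DESeq2 and 4100 without the 2 libraries whose names begin unlike the rest of their groups. With the replicate number as a block it was 4287. Transcripts higher with the fungus numbered 2092 without asymbiotic replicate 4 and 2255 without in vitro symbiotic replicate 4. Transcripts lower with the fungus numbered 1673 and 1331 without asymbiotic replicates 1 and 4, and 1380 and 1470 without in vitro symbiotic replicates 3 and 4. With library size alone 74.7% of the calls were higher with the fungus against 54.1% with TMM, and the median of all transcripts moved up by 0.19 on the log2 scale.

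**Figure D2:**
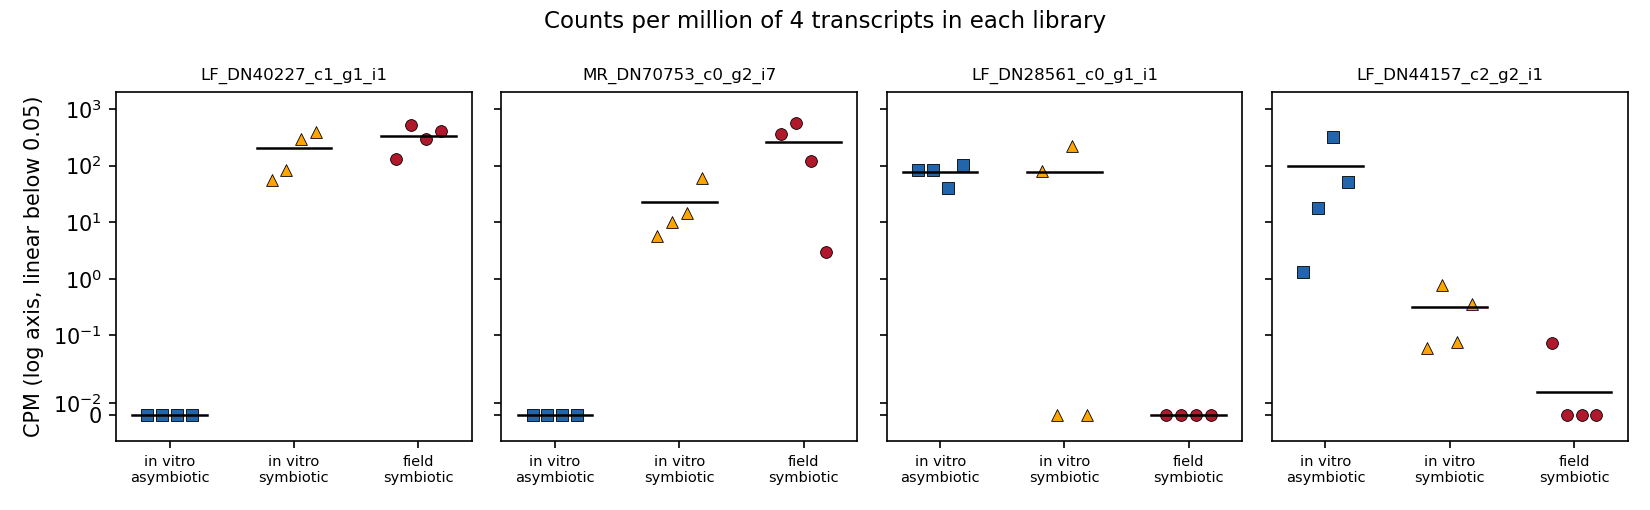
CPM, counts scaled to library size (y axis, logarithmic and linear below 0.05) of the 4 named transcripts in each of the 12 libraries, 1 point per library and a line at the group mean. TRINITY_LF_DN40227_c1_g1_i1 and TRINITY_MR_DN70753_c0_g2_i7 were at 0 in the 4 asymbiotic libraries, and TRINITY_LF_DN28561_c0_g1_i1 was at 0 in the 4 field libraries and in 2 of the 4 in vitro symbiotic libraries.

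The direct comparison of field symbiotic with in vitro symbiotic protocorms asked which transcripts differ between the growth conditions when a fungus is present in both. Whether the fungus was the same in both groups was not tested, and the oatmeal agar was present in vitro alone. The direct test called 257 transcripts higher and 260 lower in the field. This balance depended on single libraries, with 427 of 682 calls higher without field replicate 1 and 422 of 737 without in vitro symbiotic replicate 4, but 78 of 239 and 58 of 171 without in vitro symbiotic replicates 1 and 2 and 157 of 356 and 158 of 373 without asymbiotic replicates 1 and 3. Transcripts higher in the field had a median log2 fold change of 2.79 (6.91-fold) and those lower in the field a median of -2.64 (6.22-fold lower). Of the 517 transcripts called, 361 were also called in field against asymbiotic protocorms, 176 in in vitro symbiotic against asymbiotic protocorms, and 33 in neither. For 238 of them (46.0%) both symbiotic groups lay on the same side of the asymbiotic group, and 355 (68.7%) lay farther from the asymbiotic group in the field, as did 56.2% of all tested transcripts.

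None of the named transcripts was called in the direct comparison. TRINITY_LF_DN40227_c1_g1_i1 differed by a log2 fold change of 0.71 ± 0.63 (SE, edgeR adjusted p = 0.656) and TRINITY_MR_DN70753_c0_g2_i7 by 3.56 ± 1.25 (SE, edgeR adjusted p = 0.227, and 0.0172 with a log2 fold change of 5.12 without the 2 libraries whose names begin unlike the rest of their groups). The log2 fold change of this transcript was 4.71 without in vitro symbiotic replicate 4 and 2.87 without field replicate 2. TRINITY_LF_DN28561_c0_g1_i1 was at 0 in the field and at 76.1 ± 105 CPM (SD, n = 4) in vitro with the fungus (edgeR adjusted p = 0.106), with most of that level from replicate 3 (223 CPM), and DESeq2 called it (adjusted p = 2.9e-20, the lowest of 20 alternatives, which went up to 0.278). TRINITY_LF_DN44157_c2_g2_i1 was below the detection floor in the field, with 1 count in the 4 libraries together. In vitro with the fungus it had 0.321 ± 0.338 CPM (SD, n = 4), where the group floor was 0.0535 CPM (edgeR adjusted p = 0.528).

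The 517 calls were 0.908% of the transcripts tested, and 493 of them changed by at least 2-fold. The groups did not overlap for 8.71% of transcripts, where chance gives 2.86%, and 8561 transcripts had an unadjusted p below 0.05. The count was 119 and 101 without field replicates 2 and 3, 239, 171 and 311 without in vitro symbiotic replicates 1, 2 and 3, 2643 in DESeq2, 215 in a fit on the 8 libraries of these groups and 887 without the 2 libraries with other names. With the replicate number as a block it was 192. On simulated counts of the same depth and spread, edgeR recovered 24% of 4-fold and 80% of 16-fold changes in this comparison, and 32% and 26% of 4-fold changes in field and in in vitro symbiotic against asymbiotic libraries.

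The series title concerns the size of the response against its pattern. The differences of field symbiotic and of in vitro symbiotic protocorms from the same asymbiotic libraries, called field and in vitro responses here, were therefore compared. The field response may also hold the effect of growth in the field, and the in vitro response that of the medium. In both responses 2636 transcripts were higher and 1972 were lower than in asymbiotic protocorms. Only 12 transcripts were called in opposite directions. Among the 4608 transcripts called in the same direction, the change was larger in the field for 63.4% (56.2% of all tested transcripts), and the direct test called 41 of them. The 2636 transcripts higher in both had a median absolute log2 fold change of 3.11 in the field and 2.84 in vitro, and the 1972 transcripts lower in both had 1.49 and 1.44.

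A further 5883 transcripts were called in the field response alone and 1857 in the in vitro response alone. The direct test called 308 (5.24%) of the former and 6.62% of the latter, so for the others a difference between the responses was not shown.

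The shared asymbiotic libraries can raise such overlaps. Independent lists of these sizes would share 353 higher and 249 lower transcripts and oppose 593. Simulated groups with no effect had 0 calls and so shared 0, which does not measure the part of the shared libraries. With the asymbiotic libraries split into disjoint pairs, 1 pair for each response, a mean of 797 transcripts were higher in both (645 to 934 over 6 splits) and 505 lower in both (412 to 618), where independent lists give 59.6 and 39.4. The number called in opposite directions was then 13.3 on average (8 to 25).

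Across all 56924 tested transcripts, which are not independent replicates, the log2 fold changes of the field and in vitro responses had a Pearson correlation of 0.828 (jackknife SE 0.0591 over libraries). Simulated groups without any effect gave 0.498, because both responses use the same asymbiotic libraries. The covariance of the responses was 1.89 against 0.173 without effects, a difference of 1.71, and the correlation with simulated noise variance and covariance taken out was 0.889. With disjoint pairs of asymbiotic libraries the uncorrected correlation was 0.661 (0.630 to 0.694 over 6 splits), against a mean of 0.0173 for simulated groups without effects split likewise. The signs of the fold changes agreed for 76.6% of transcripts against 66.7% without effects. With disjoint asymbiotic pairs they agreed for 67.8 to 69.0%, against 50.1% without effects.

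**Figure D3:**
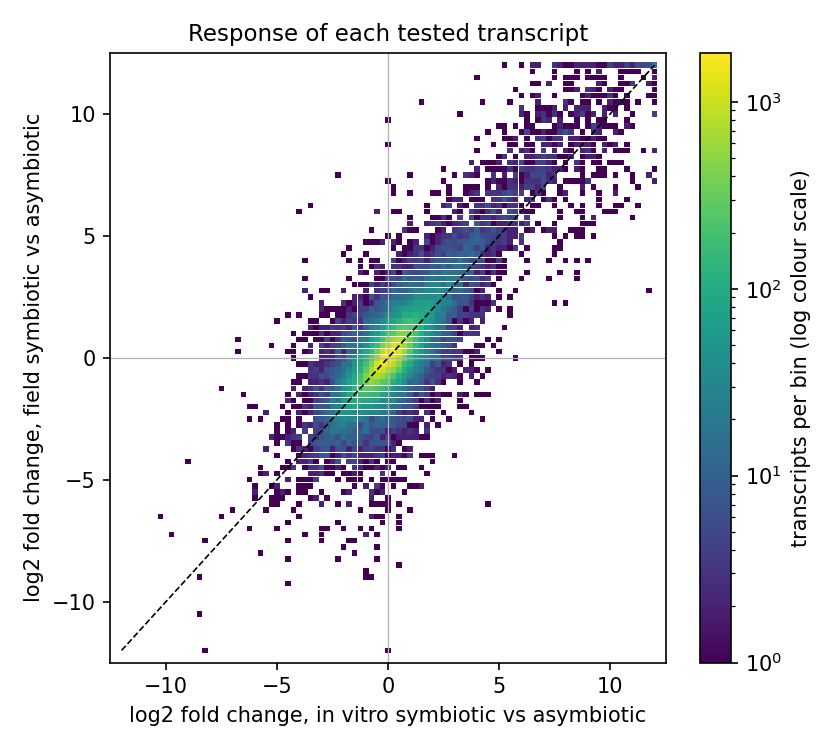
Log2 fold change in vitro symbiotic against asymbiotic (x axis) and field symbiotic against asymbiotic (y axis) of the 56924 tested transcripts, with colour for the number of transcripts per bin on a logarithmic scale and values beyond 12 drawn at the edge. The dashed line marks equal change, and the correlation across transcripts was 0.828, with 0.498 for simulated groups without effects.

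The SD of log2 fold changes over all tested transcripts was 1.62 in the field response and 1.41 in the in vitro response. After subtraction of the variance simulated without effects, 0.588 as an SD for each, the field response was 1.18 times the size of the in vitro response (jackknife SE 0.177). The simulation gave each group the same dispersion. The square root of the mean within-group variance of log2 CPM was however 0.705 in field and 0.826 in in vitro symbiotic libraries. The subtraction may thus have been too small for the in vitro response, which would hold the ratio too low. This SE took the 12 libraries as 1 sample and not as 3 groups of 4, so it is approximate. The ratio exceeded 1 by about this SE, so a ratio above 1 was not shown. Estimated from log2 CPM of disjoint sets of libraries, without simulated noise, the ratio was 1.26. With simulated noise it was 1.34 without in vitro symbiotic replicate 4 and 1.10 without in vitro symbiotic replicate 1, the lowest value with a library left out.

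Each library was also placed on an axis from the asymbiotic mean (0) to the field mean (1), using 10702 transcripts selected from the field and asymbiotic libraries alone. The in vitro symbiotic libraries, which had no part in that selection, lay at 0.477, 0.553, 0.796 and 0.927 for replicates 1 to 4. The field libraries ranged from 0.973 to 1.02 and the asymbiotic libraries from -0.043 to 0.025, but their means set the ends of the axis and its transcripts were selected on them, so their narrow ranges were partly built in. The order of the 4 libraries was the same for transcripts higher in the field (0.467, 0.531, 0.745 and 0.911) and for transcripts lower in the field (0.507, 0.619, 0.957 and 0.978).

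**Figure D4:**
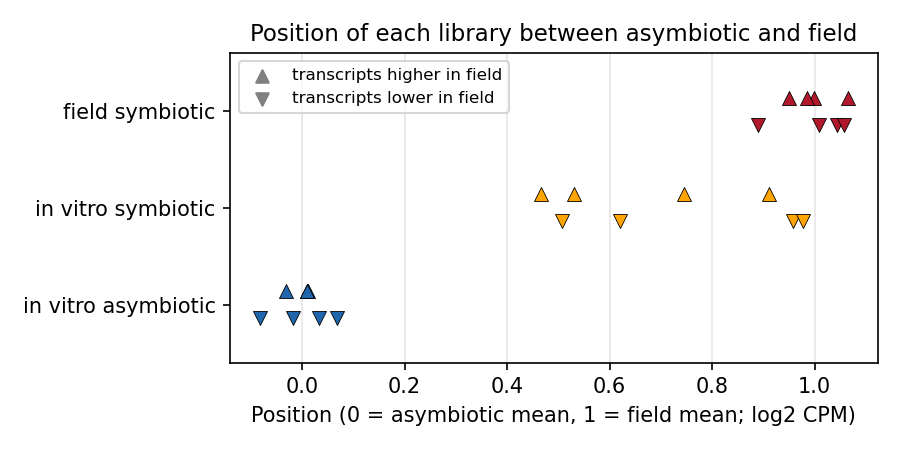
Position of each library (x axis, in units of the distance from the asymbiotic mean at 0 to the field mean at 1, on log2 CPM) by group, with upward triangles for transcripts higher in the field and downward triangles for transcripts lower in the field. The in vitro symbiotic libraries range from 0.467 to 0.978.

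The most abundant transcripts took a larger share of the counts in asymbiotic protocorms. The 100 most abundant transcripts of each library held 15.9 ± 0.82% (SD, n = 4) of counts in asymbiotic, 12.8 ± 0.27% in in vitro symbiotic and 11.4 ± 0.50% in field libraries. No values of any pair of these groups overlapped (exact two-sided permutation test, p = 0.0286 for each pair, the smallest p that 4 against 4 libraries allow, adjusted p = 0.0612 over 15 tests), so the differences did not pass 0.05 after adjustment. The number of transcripts detected was 92534 ± 1581 (SD) in field and 88779 ± 1981 in asymbiotic libraries (exact p = 0.0571, adjusted p = 0.107).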

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

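Among the tests of this part, those of RNA from other organisms and the separate mixture tests of replicates 1 to 3 and of replicate 4 were chosen after the values had been seen. Single libraries stood apart in 6 of 33 sets of 4 values checked, where chance gives about 1 in 20 for normally distributed values. That rate need not hold for the CPM of single transcripts, and several of these measures are related. An excess over chance was thus not shown.

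In vitro symbiotic replicate 4 stood apart from the rest of its group in 4 measures. It had 87406 transcripts detected, against 90830 to 91488 in replicates 1 to 3, and was the shallowest library of its group. Its 100 most abundant transcripts held 13.2% of counts, against 12.6 to 12.7%. Its second principal component score was 143.1, against 81.0 to 87.7. Its level of TRINITY_MR_DN70753_c0_g2_i7 was 59.4 CPM, against 5.71 to 14.4 CPM. For TRINITY_LF_DN44157_c2_g2_i1, asymbiotic replicate 3 had 317 CPM against 1.31 to 51.1 CPM in the others, and field replicate 1 had 0.0730 CPM, which is a single count, against 0.

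The direct test called 517 transcripts as different between field and in vitro symbiosis, and 12 transcripts were called in both responses in opposite directions.

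The counts of calls were set against other ways to divide the same 8 libraries into 4 and 4, each division refitted on those libraries alone with its own filter. For field against asymbiotic, only 1 of 35 divisions, the real one, called as many transcripts (10759, highest other 2). For in vitro symbiotic against asymbiotic it was also 1 of 35 (4466, highest other 4), and for field against in vitro symbiotic 1 of 35 (248, highest other 7). An accidental division of exchangeable libraries is therefore excluded at 0.05 for each comparison.

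A set of 124 transcripts was at 0 in each of the 4 asymbiotic libraries and at 10 or more counts in each of the 8 symbiotic libraries. TRINITY_LF_DN40227_c1_g1_i1 and TRINITY_MR_DN70753_c0_g2_i7 belong to this set. The mirror pattern was shown by 0 transcripts, but it asks for 0 in 8 libraries and presence in 4, so these numbers are not directly comparable. The planned test of shallow asymbiotic libraries decides nothing: at the level of the lowest symbiotic library a median of 145 counts would be expected in the asymbiotic group, but the definition of the set alone puts that number at 40.6 or more. RNA of a single other organism stays open: the share of a transcript in the set varied over the symbiotic libraries with a median SD of 1.15 on the log2 scale, more than the 0.525 to 0.705 of 100 sets of equally abundant transcripts that rose but were detected without fungus, but an organism can also change its own expression between samples. RNA of several other organisms, such as different fungi, was predicted to give more closely correlated pairs. Of the transcript pairs, 2.01% had a correlation above 0.95 over the symbiotic libraries, against at most 0.774% in those 100 sets. Those sets were matched on mean level alone and varied less. Transcripts of 1 organism that are regulated together would also give such pairs, so the test cannot decide. Plant transcripts that are switched on by symbiosis, the difference that the design names, remain an open and untested explanation, and so does the change of medium.

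The 4 in vitro symbiotic libraries were spread from 0.477 to 0.927 on the axis from asymbiotic to field protocorms. Their totals fell from replicate 1 to replicate 4 as their positions rose. The number of reads alone is argued against, because thinning each library to the same total left the range at 103% of its size. Thinning cannot speak to other traits of the libraries that go with depth. A mixture of field-like and asymbiotic-like tissue predicts that the relative levels of strongly induced and strongly repressed transcripts add up to about 1. The highest sum in replicates 1 to 3 was 0.420 (bootstrap over transcripts 0.385 to 0.455), which argues against a mixture there. That interval does not measure the spread between libraries. The transcripts were also selected on the field and asymbiotic means used as references, which can lower the sums of other libraries. In replicate 4 the sum was 0.833, and a mixture cannot be told apart from a field-like state, because the sums of the field libraries themselves were 0.719 to 1.24. Apart from library names, whose meaning is not given, the labels give no difference between these replicates, so no biological explanation was tested. The name of replicate 4, which lay nearest the field libraries, begins unlike those of replicates 1 to 3.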

How the results depend on the processing

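Leaving out the 2 libraries with other names, summing transcripts of a Trinity gene and the estimate from disjoint sets of libraries were chosen after seeing the data. Of 108 alternative values of the counts, the correlation and the ratio, 89 stayed near the reported value (counts within 1.5-fold, the others within 1 jackknife SE), 19 moved and 0 reversed. The jackknife SE came from the values with libraries left out in turn, so those values of the correlation and the ratio could hardly move beyond it. Counts of calls could not be labelled reversed. This tally thus does not measure how stable the results were. Of 240 alternative values for the named transcripts, 236 kept their call or its absence, 2 lost it, 2 gained it and 0 reversed. With libraries left out in turn, field against asymbiotic gave 7227 to 11351 calls, in vitro symbiotic against asymbiotic 3423 to 7430, field against in vitro symbiotic 101 to 737, the correlation 0.790 to 0.840 and the ratio of response sizes 1.10 to 1.34; the cause was not tested. Without a filter the correlation was 0.621 and the ratio 1.46, with many transcripts of few counts added. Fits on the compared groups alone gave 215 calls for field against in vitro symbiotic, and they cannot give the correlation or the ratio. DESeq2 called 10076 for in vitro symbiotic against asymbiotic and 2643 for field against in vitro symbiotic, and it called TRINITY_LF_DN28561_c0_g1_i1 in the latter (adjusted p = 2.9e-20, over all alternatives up to 0.278); the cause was not tested. Without the libraries with other names these counts were 4100 and 887 and the correlation 0.761, and TRINITY_MR_DN70753_c0_g2_i7 passed in field against in vitro symbiotic (adjusted p = 0.0172, up to 0.481 over the others). The letters in the library names may mark a batch, but each other name stands for 1 library, so no value within such a batch can be given.

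A pairing of the samples by replicate number was neither shown nor excluded. Deviations of the 12 pairs with the same number correlated at -0.153 to 0.169, 2 of them above 0.1, and 5 of 12 libraries correlated best with their own number. With a replicate block, calls were 8278, 4287 and 192 in the order above, and TRINITY_MR_DN70753_c0_g2_i7 had an adjusted p of 0.0660 in in vitro symbiotic against asymbiotic (the highest of 20 alternatives, down to 1.0e-08).

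Gene lists gave no value under any alternative. Totals ranged from 9353301 to 23145905 counts, and 2-fold changes were rarely recovered on simulated counts with 200 transcripts changed (6, 0 and 0% in the order above).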

Other observations

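All tests in this part were run on patterns seen in the data, though the bounds for the deviations shared by replicate 1 were written before those values were computed.

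The 124 transcripts absent from asymbiotic libraries belonged to 116 Trinity genes, and 120 of them (96.8%) carried the prefix MR, as did 65.2% of the tested transcripts. They held 0.479, 0.742, 0.419 and 0.549% of counts in field replicates 1 to 4 and 0.120, 0.166, 0.247 and 0.685% in in vitro symbiotic replicates 1 to 4. All 124 were called in field against asymbiotic protocorms, which the definition of the set on the same counts nearly fixed in advance. Grouped by their correlation over the symbiotic libraries (average linkage at 0.8), 96 of them fell into 7 blocks of at least 5 transcripts. The largest block, of 30 transcripts, summed to 2423, 4296 and 1726 CPM in field replicates 1 to 3 and to 234 CPM in field replicate 4, and to 229, 319, 329 and 1279 CPM in in vitro symbiotic replicates 1 to 4. A block of 11 transcripts went the other way among the field libraries, with 1847 CPM in replicate 4 and 264 to 584 CPM in replicates 1 to 3.

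The prefix MR was carried by 72.5% of the transcripts higher in the field than in asymbiotic protocorms and by 53.3% of those lower. In in vitro symbiotic against asymbiotic protocorms these shares were 74.6 and 48.6%. Transcripts with the prefix LF held 48.2 ± 0.24% (SD, n = 4) of counts in asymbiotic, 46.1 ± 1.30% in in vitro symbiotic and 45.3 ± 0.57% in field libraries. The asymbiotic libraries did not overlap with either symbiotic group in this share (exact two-sided p = 0.0286 each, adjusted p = 0.0612 over 15 tests, which does not pass 0.05 after adjustment).

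Some transcripts were at 0 in one library of a group and at 50 or more counts in another. There were 632 such transcripts in asymbiotic, 587 in in vitro symbiotic and 214 in field libraries. TRINITY_LF_DN28561_c0_g1_i1 is an example, with 1374 and 2862 counts in in vitro symbiotic replicates 1 and 3 and 0 counts in replicates 2 and 4. The square root of the mean variance of log2 CPM within a group was 0.705 in field, 0.757 in asymbiotic and 0.826 in in vitro symbiotic libraries.

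Asymbiotic replicate 1 and in vitro symbiotic replicate 1 deviated together from their group means (correlation across transcripts 0.169, the highest of 48 pairs of libraries from different groups, while asymbiotic replicate 1 and in vitro symbiotic replicate 2 had -0.198). A shift along the axis from asymbiotic to field is argued against, because the correlation was 0.182 with that axis taken out. A shared seed genotype may contribute, and it predicts a higher correlation on transcripts that are on in some libraries and off in others. The correlation was higher there by 0.109 (1051 transcripts, bootstrap over transcripts 0.0515 to 0.162), and the predicted excess of 0.1 lies inside that interval. Other pairs also had larger correlations there (0.193 against 0.120 for asymbiotic replicate 4 and in vitro symbiotic replicate 2), so the excess was not particular to this pair and the explanation stays open. The same replicate numbers of the asymbiotic and in vitro symbiotic groups did not match beyond chance (exact one-sided permutation p = 0.125 over 24 matchings, mean correlation 0.0742).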
